A study of Homo sapiens with 12 samples.

How the data were processed

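Total RNA was taken from HSC-3 cells, 4 libraries for each of 3 groups (untreated, CPA, CPA with synta-66), and each library has 1 file of counts per gene. Per the labels' protocols, the run gave 774131516 raw paired-end reads, of which 708579673 remained after trimming (46791160 to 66701914 per sample). They name FastQC 0.11.5, Trimmomatic 0.32, STAR 2.5.2a with the Ensembl 84 annotation of GRCh38, and HTSeq 0.6.1p1 with the library taken as stranded. The submitters' processing notes give Trimmomatic 0.36. The library kit is not named in the sources used here. The deposited values are raw counts of reads per gene and were not normalized by the authors. The study kept genes with at least 5 reads in 2 of 4 libraries of a group and called genes with DESeq2 1.28.1 at 5% FDR and 1.5-fold, per the series' design text.

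Each file has 60675 gene rows and 5 closing rows of reads not assigned to a gene, which were left out of library sizes and tests. Between 90.5% and 96.3% of the uniquely aligned reads fell in no annotated feature, and 3.58% to 9.4% were assigned to genes. Non-unique alignments were between 44.2 M and 486 M. Uniquely aligned reads reached 108 M in a library, above the 66.7 M trimmed reads that the labels give as the highest sample, so the 2 reads of a pair appear to have been counted singly and a count is not a count of fragments. Of the gene IDs, 56558 were matched in GENCODE 44, and 4117 were not. The unmatched rows held 9.78% of gene reads.

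Of all gene reads, 64.4% lay at features opposite an exon of a coding gene, 18.1% at the 2 mitochondrial ribosomal RNAs, 4.36% at features with no opposite exon and 3.31% opposite a noncoding exon. Because of this, a coding gene was read at a feature when that feature overlapped exons of this 1 coding gene on the other strand by at least 30 bases in GENCODE 44, taking the feature with the most reads. This gave 3958 genes and 4618 features. The assignment and its overlap minimum were chosen after seeing the data. A feature's own transcript cannot be separated from that of the gene opposite it. Coordinates are those of GENCODE 44 on GRCh38, from 1.

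Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the study's filter of 5 reads, 1 quasi-likelihood fit of all 12 libraries with the group as the only term, and Benjamini-Hochberg adjustment over 14911 genes. A call needs adjusted p under 0.05 and a change of at least 1.5-fold. Changes are log2 fold changes with SE, and CPM values use TMM-scaled library sizes. The design, its alternatives, 21 gene lists and the rule for named genes were set before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 if at least 3 members were tested. The rule for named genes takes, in each comparison, the 8 largest rises and 8 largest falls among called coding genes with a mean of at least 5 CPM and no overlap between groups, up to 4 called members of each list with a mean of at least 1 CPM, the 8 genes raised and 8 lowered by CPA with the largest effect that synta-66 reversed, and 13 genes whatever their values. For length, some of these are not in the text. CALR, PDIA6, PPIB, EDEM1 and the other members of a list named beside its test follow from that list. The same rule was applied again to genes read at opposite features, which was not planned. The own counts of genes that had more reads of their own than at the opposite feature in untreated cells were also added after seeing the data.

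The lists were endoplasmic reticulum chaperones and degradation, ATF4 and CHOP stress response, immediate early genes, NFAT and calcineurin targets, CREB targets, cytokines and chemokines, NF-kB targets, matrix proteases and invasion, pain mediators, angiogenesis and hypoxia, calcium entry and handling, EGFR ligands and MAPK feedback, cholesterol synthesis, G1 and S phase genes, G2 and M phase genes, keratinocyte differentiation, basal epithelium and EMT, heat shock, interferon response, and markers of fibroblasts and of immune and endothelial cells.

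The steps were tested on simulated data in which 200 of 14911 genes changed. For CPA against untreated, 3, 19, 28 and 39 of 50 genes changed by 1.5, 2, 4 and 8-fold were recovered, with 4 false calls. For CPA with synta-66 against CPA these were 5, 15, 36 and 38 with 7 false calls, and for CPA with synta-66 against untreated 7, 15, 30 and 41 with 4. A list raised 1.5-fold was called in each comparison and no other list was. The simulated genes varied independently of each other, so few false list calls were bound to follow. How the list test behaves with correlated genes was not simulated.

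The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, filterByExpr or no filter, no minimum fold, a test against the minimum fold, a fit of 2 groups only, the replicate number as a block, and each library left out in turn. For lists they were an estimated correlation and fry. Added after seeing the data were the fit without the 3 libraries richest in non-unique alignments (untreated replicate 3, CPA with synta-66 replicates 1 and 4) and the fit without mitochondrial genes and unmatched rows. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom between pairs was at least 5.26. Intervals and floors take each read as an independent count and leave out all other spread. Where the 2 reads of a pair were counted singly, the intervals are too narrow even for counting error.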

Results

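RNA was sequenced from HSC-3, a human oral squamous carcinoma cell line, in 3 groups of 4 libraries: untreated cells, cells given 25 µM cyclopiazonic acid (CPA) for 3 hours, and cells given CPA with synta-66. CPA blocks the SERCA pump that fills the endoplasmic reticulum with calcium, and emptied stores open ORAI calcium channels in the plasma membrane. Synta-66 inhibits ORAI channels. Its dose is not given in the sources used here, and no group with synta-66 alone was analysed here. The 12 libraries held between 2819486 and 5458858 reads assigned to genes, out of 52.5 M to 108 M uniquely aligned reads, and 14911 genes were tested. The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

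Of 13 abundant or commonly used coding genes examined, 8 had far more reads at an annotated feature on the opposite strand than at their own locus, 1 had fewer there and 4 had no such feature. GAPDH, a glycolytic enzyme, had a mean of 92.3 reads at its own locus (chromosome 12, 6534512 to 6538374) and 149000 at the noncoding feature ENSG00000269968 that overlaps it on the other strand by 422 bases. FTH1, a ferritin subunit, had 13.2 reads against 22000 at BEST1, and the keratin KRT18 had 153 against 30500 at KRT8. ACTB, the cytoskeletal actin, TUBA1B, KRT5 and KRT14 had no opposite feature and few reads of their own, with between 30 and 96 per library for ACTB and 51 and 172 for TUBA1B. EEF1A1 went the other way, with 54.2 reads of its own and 18.7 at MTO1, which overlaps it by only 119 bases. Of 1989 pairs of a noncoding feature and the single coding gene opposite it, 1528 (76.8%) had more reads at the noncoding feature, with a median ratio of 11.1. Pairs entered only if the noncoding feature passed the count filter, which was not asked of the coding gene. This choice pushes both values up. For each coding gene with such a feature, the text therefore also gives the change "read at" the feature opposite it, an assignment made for 3958 genes after the counts had been seen. It cannot separate the feature's own transcript from that of the gene opposite it. Across 242 genes with 2 such features, the log2 fold changes at the pair correlated with r = 0.584 for CPA against untreated and r = 0.633 for CPA with synta-66 against CPA, and the highest r of 1000 shuffles was 0.192 and 0.205. These are correlations across genes, which are not independent replicates. Both features of a pair lie on the same strand over the same gene. Their agreement therefore does not show that they read the gene opposite them. For genes called at the opposite feature, the gene's own count followed less closely, with r = 0.177 over 107 genes and r = 0.329 over 155. Of the 140, 226 and 142 genes called at an opposite feature in the 3 comparisons with their own count also tested, the own count was called the same way for 4, 21 and 13 and the other way for 3, 4 and 1. Of 48 genes given in this way in the text (ORAI2 and STIM1 left out), 39 were also tested by their own counts. Of these, 8 (ANKRD37, CEMIP, CSPG4, HSP90B1, IL16, NUDT6, SYVN1 and TPPP) had more reads of their own in untreated cells. By the same rule, the own counts of all of these 8 but CSPG4 are also the readings of the genes opposite them. Those genes are UFSP2, MESD, UQCC6, STARD5, FGF2, MRPL49 and CEP72, in the same order. Such an own count cannot be separated from the transcript of the gene opposite it. A low own count may also not show a gene's expression.

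**Figure D1:**
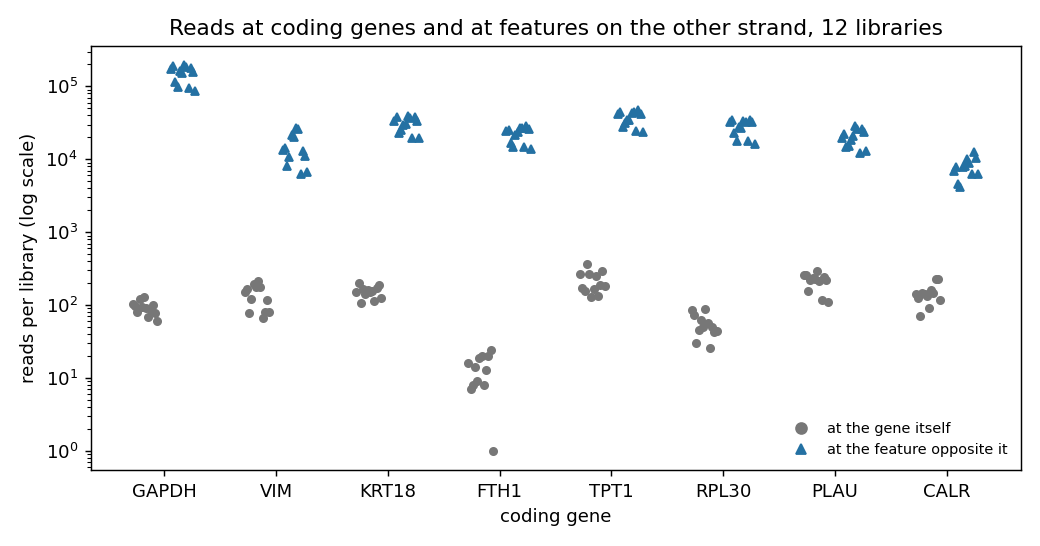
Reads per library (log scale) at 8 coding genes (grey circles) and at the feature on the strand opposite each of them (blue triangles), 1 point per library for 12 libraries. The mean at the gene itself was between 0.0603% and 1.84% of the mean at the opposite feature.

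The first comparison asks what emptying the calcium stores with CPA did to expression. Read at opposite features, the signalling-induced nuclear receptor NR4A1 rose from 5 ± 2.21 to 53.6 ± 7.93 CPM (SD, n = 4), the membrane protein MYADM from 13.1 ± 1.78 to 288 ± 25.5 CPM, and CEMIP, a protein of hyaluronan turnover, from 1.81 ± 0.589 to 35.9 ± 4.21 CPM. The tubulin-binding protein TPPP, read at CEP72, had the highest log2 fold change among called coding genes with a mean above 5 CPM, at 5.03 ± 0.45 (SE). By their own counts CEMIP went from 14.3 ± 2.1 to 23.4 ± 5.43 CPM (adjusted p = 0.0645, but called without CPA with synta-66 replicate 2, at 0.0455). TPPP had 64 ± 8.48 and 48.4 ± 13.8 CPM of its own (adjusted p = 0.113), and was called lower without CPA replicate 2 (-0.61, adjusted p = 0.00528). Again at opposite features, the MAPK phosphatase DUSP6 fell from 880 ± 86.2 to 380 ± 29.1 CPM, and the cystine transporter SLC7A11 from 238 ± 37.1 to 125 ± 3.42 CPM. In all, 269 genes rose and 156 fell by at least 1.5-fold at adjusted p under 0.05, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and of the 3958 genes read at an opposite feature 136 rose and 52 fell. The adjusted p was 8.81e-14 for NR4A1, 3.87e-25 for MYADM, 3.46e-15 for DUSP6 and 1.72e-09 for SLC7A11.

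The feature behind NR4A1 was NR4A1AS (chromosome 12, 52058459 to 52059503). MYADM was read at ENSG00000232220 (chromosome 19, 53874626 to 53876049), CEMIP at MESD (chromosome 15, 80946289 to 80989828), DUSP6 at ENSG00000274021 (chromosome 12, 89351015 to 89353271) and SLC7A11 at SLC7A11-AS1 (chromosome 4, 138057464 to 138178177), all in GRCh38. Other rises read in this way included the melanoma antigen CSPG4 (log2 fold change 2.60 ± 0.43) and the scaffold protein NEDD9 (2.36 ± 0.20). Falls included ALPK2 (-1.69 ± 0.21), IL16 read at STARD5 (-1.73 ± 0.30), NUDT6 read at FGF2 (-1.50 ± 0.25), ITGBL1 read at FGF14 (-1.32 ± 0.15) and PRICKLE1 (-1.21 ± 0.19). The own count of CSPG4 was larger than its opposite feature in untreated cells, at 9.88 ± 1.34 against 2.12 ± 0.983 CPM, and was not called (-0.21 ± 0.36, adjusted p = 0.865). The own count of IL16 rose (0.99 ± 0.09, adjusted p = 1.27e-10), against the fall at STARD5, and that of NUDT6 was not called (0.30 ± 0.11, adjusted p = 0.102). By the rule used here these counts are also the readings of STARD5 and FGF2, in that order, so neither need be the gene's own transcript. Among genes named by their own counts, IL17RC rose by 3.14 ± 0.42 on the log2 scale, from 1.08 to 9.88 CPM. PARP12 rose by 2.47 ± 0.45, from 1.9 to 10.6 CPM. HIF1A had -1.33 ± 0.22 and the hexokinase HK2 -0.80 ± 0.18. Such low own counts may not show these genes' expression. HIF1A read at its opposite feature was not called (0.08, adjusted p = 0.731 in the edgeR test).

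Gene lists were fixed before the data were examined, and testing them at opposite features was added afterwards. Of 12 members of the endoplasmic reticulum chaperone and degradation list read at an opposite feature, 3 rose and none fell: HSP90B1 (2.05 ± 0.14), the ubiquitin ligase SYVN1 (1.05 ± 0.20) and the chaperone HYOU1 (0.72 ± 0.07), and 3 also rose adjusted over the list alone. The list rose as a whole (camera, adjusted p = 5.26e-05; adjusted p = 0.0151 with an estimated correlation). The own counts of HSP90B1 (0.032 ± 0.161, adjusted p = 0.963) and SYVN1 (0.065 ± 0.13, adjusted p = 0.891) were not called. By their own counts 2 of 25 members rose, 3 adjusted over the list alone, and the list was not called (adjusted p = 0.25), but was without untreated replicate 4 (0.0355). Of 6 pain mediators read at opposite features, the cytokines LIF (1.94 ± 0.35) and IL6 (1.29 ± 0.22) rose, the same number adjusted over the list alone, and the list had adjusted p = 0.00573 and adjusted p = 0.0428 with an estimated correlation. The own count of IL6 went the other way, from 6.79 ± 4.06 to 2.36 ± 1.18 CPM, and was not called (-1.49 ± 0.47, adjusted p = 0.0582). Of 5 angiogenesis and hypoxia genes read so, LOX, the collagen cross-linking enzyme (1.62 ± 0.20), and ANKRD37 (1.35 ± 0.17) rose, and 2 adjusted over the list alone (list adjusted p = 0.00492; adjusted p = 0.0428 with an estimated correlation). By its own count ANKRD37 was not called (0.30 ± 0.10, adjusted p = 0.0706). Of 6 CREB targets read so, NR4A1 and the clock gene PER2 (1.19 ± 0.32) rose, 3 adjusted over the list alone (list adjusted p = 0.00492; adjusted p = 0.0428 with an estimated correlation). By own counts these 3 lists were not called (adjusted p = 0.954 each): of 14 pain mediators and 7 CREB targets none was called, and of 19 angiogenesis and hypoxia genes none rose and 2 fell, HIF1A and HK2. The call for PER2 ended without untreated replicate 1 (adjusted p = 0.0527), untreated replicate 3 (0.0899) or CPA replicate 1 (0.0578).

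Of 5 G2 and M phase genes read at opposite features, 3 fell, among them the mitotic kinase PLK1 (-0.64 ± 0.12) and HMMR (-0.67 ± 0.12), 3 adjusted over the list alone, and the list fell (adjusted p = 0.000331; adjusted p = 0.0211 with an estimated correlation). By their own counts, 1 of 22 members of this list fell and the list had adjusted p = 0.0366, but adjusted p = 0.596 with an estimated correlation and 0.051 with the replicate number as a block. That call also ended without untreated replicate 4 (adjusted p = 0.0962) or CPA replicate 1 (0.0561), 3 (0.0859) or 4 (0.0736). Read at opposite features, the intermediate filament vimentin (VIM) rose from 2820 ± 254 to 5330 ± 446 CPM and HMGCS1 of cholesterol synthesis from 416 ± 41 to 904 ± 57.1 CPM. The own count of VIM went from 31.1 to 43.7 CPM and was not called, and HMGCS1 was not tested by its own count. The lists they belong to, basal epithelium and EMT (adjusted p = 0.0277) and cholesterol synthesis (adjusted p = 0.00533), had adjusted p = 0.115 and adjusted p = 0.105 with an estimated correlation, and matrix proteases and invasion, with no member called, went from adjusted p = 0.0419 to adjusted p = 0.105. By own counts no member of these 3 lists was called, and the lists had adjusted p = 0.715, 0.954 and 0.715. Leaving out untreated replicate 1 or 2, CPA replicate 2, 3 or 4 or CPA with synta-66 replicate 2 ended the protease call, with adjusted p between 0.0502 and 0.0778. Genes outside the called lists also moved at opposite features: IER3, an immediate early gene, rose from 1420 ± 86.2 to 2790 ± 144 CPM, the NF-kB inhibitor TNFAIP3 by 0.87 ± 0.12 and cyclin CCNE2 by 0.96 ± 0.08 on the log2 scale. Without the 3 libraries richest in non-unique alignments, a setting chosen after seeing the data, the epithelium and protease lists had adjusted p = 0.0573. PLK1 and the cyclin CCNA2 (-0.61 ± 0.12), read at opposite features, lay near the fold minimum, and fell short of it, PLK1 without CPA replicate 2 (-0.575) and CCNA2 without untreated replicate 3 (-0.507), untreated replicate 4 (-0.534) or CPA replicate 1 (-0.55). Mitochondrial ribosomal RNA took 16.1% ± 16.5 of gene reads in the untreated and 3.22% ± 4.22 in the CPA libraries (SD, n = 4). These means were 8.21% without untreated replicate 3 and 1.16% without CPA replicate 1. Without the 3 libraries 273 genes rose, 136 fell and 351 of the 425 calls remained.

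The second comparison asks which part of the CPA response the ORAI inhibitor altered. Read at opposite features, with synta-66 NR4A1 was at 2.44 ± 1.09 CPM against 53.6 ± 7.93 with CPA alone, MYADM at 13.7 ± 4.84 against 288 ± 25.5, CEMIP at 1.79 ± 1.24 against 35.9 ± 4.21 and VIM at 2760 ± 180 against 5330 ± 446. DUSP6 rose to 925 ± 76.4 CPM and SLC7A11 to 367 ± 40.7. CYP1B1, a cytochrome P450 that CPA alone left at 36.3 ± 3.36 CPM against 35.2 ± 7.41 untreated, fell to 4.87 ± 1.38 CPM with synta-66, read at CYP1B1-AS1. The own count of CYP1B1 was at most 1 CPM in each group mean and was not called. By its own count CEMIP had 23.4 ± 5.43 CPM with CPA and 18.4 ± 4.48 with synta-66, and was not called (-0.36 ± 0.22, adjusted p = 0.414 in the edgeR test). The own count of VIM was called lower (-0.704 ± 0.175, adjusted p = 0.00636). In the same edgeR test, 289 genes were higher and 421 lower with synta-66 than with CPA alone, and 107 and 173 of the genes read at opposite features. The adjusted p was 1.37e-15 for NR4A1, 6.57e-25 for MYADM, 1.06e-12 for VIM, 5.02e-16 for DUSP6 and 4.21e-13 for CYP1B1.

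Of 6 immediate early genes read at opposite features, 3 fell, NR4A1 (-4.53 ± 0.29), IER3 (-1.42 ± 0.07) and JUNB (-0.66 ± 0.11), and the list fell (adjusted p = 0.0202; adjusted p = 0.109 with an estimated correlation). By own counts none of 17 immediate early genes was called, and the list had adjusted p = 0.915. Single genes of other lists that fell, read at opposite features, were OVOL1 of keratinocyte differentiation (-1.82 ± 0.15), TNFAIP3 (-1.25 ± 0.13), the cytokine IL24 (-1.01 ± 0.25), LOX (-0.83 ± 0.20), the integrin ITGA5 (-0.65 ± 0.12) and LIF (-1.11 ± 0.34). The call for LIF, at adjusted p = 0.0367, ended without CPA replicate 2 (0.0511), CPA replicate 3 (0.212) or CPA with synta-66 replicate 2 (0.0993), 3 (0.119) or 4 (0.075). ITGA5 fell short of the fold minimum without CPA with synta-66 replicate 3 (-0.583). IL6 read at its opposite feature was not called (0.47, adjusted p = 0.18), while its own low count rose (1.66 ± 0.47, adjusted p = 0.0205), a call that ended without CPA replicate 4 (0.0882) or CPA with synta-66 replicate 2 (0.0558) or 4 (0.0752).

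Genes of the stress response were higher with synta-66 than with CPA alone. The ATF4 and CHOP list had not been called for CPA against untreated, by own counts (median log2 fold change -0.161, adjusted p = 0.375) or at opposite features (adjusted p = 0.36). The list at opposite features leaves out DDIT3, the gene of CHOP, since the feature MARS1 opposite it also lies opposite ARHGAP9. By their own counts 5 of 21 members of the ATF4 and CHOP list rose, 7 adjusted over the list alone, including CEBPB (1.44 ± 0.26) and the serine pathway enzyme SHMT2 (1.65 ± 0.32), and the list rose (adjusted p = 1.19e-06; adjusted p = 0.0247 with an estimated correlation). The own count of SHMT2 went from 5.61 ± 1.42 to 17.4 ± 3.48 CPM. By the rule used here it is also the reading of NDUFA4L2, by an overlap of 33 bases. At opposite features 2 of 8 rose, SLC7A11 (1.55 ± 0.10) and CEBPB (0.82 ± 0.17), with list adjusted p = 0.0202 and adjusted p = 0.109 with an estimated correlation. Of the 12 endoplasmic reticulum genes read at opposite features, HYOU1 (1.03 ± 0.07) and HSP90B1 (0.78 ± 0.13) rose, and adjusted over the list alone 2 rose and 1 fell. The list had adjusted p = 0.0053, but adjusted p = 0.0764 with an estimated correlation. By their own counts 7 of 25 members of that list rose and 2 fell, 7 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.0672). It was called without untreated replicate 4 (0.0279), CPA replicate 1 (0.0124) or CPA with synta-66 replicate 2 (0.0171). By its own count the main endoplasmic reticulum chaperone HSPA5 rose from 9.84 ± 5.7 to 34.1 ± 8.77 CPM and PDIA4 from 4.33 ± 1.38 to 18.1 ± 4.22 CPM. Abundant genes such as ACTB also had few reads of their own. Changes in low own counts, here and in the list tests by own counts, may therefore not be changes in the genes' expression. Others that rose by their own counts were the EGFR ligand AREG (2.21 ± 0.38), the receptor kinase RET (2.41 ± 0.43) and the hormone gene ERFE (2.08 ± 0.23), and the keratin KRT15 fell (-3.13 ± 0.49). The EGFR ligand and MAPK feedback list rose by own counts (2 of 18 members, 4 adjusted over the list alone, adjusted p = 0.02; adjusted p = 0.0863 with an estimated correlation), and not without CPA with synta-66 replicate 1 (0.0544) or 3 (0.0595). At opposite features cholesterol synthesis fell (adjusted p = 0.021) and G2 and M phase genes rose (adjusted p = 0.028), with adjusted p = 0.173 and adjusted p = 0.109 with an estimated correlation. By own counts none of 15 cholesterol genes was called and 1 of 22 G2 and M phase genes rose, and the lists had adjusted p = 0.982 and 0.174. Both calls at opposite features ended without CPA with synta-66 replicate 1 (0.0657), and that of G2 and M phase genes without CPA replicate 3 (0.067).

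Of the 4 synta-66 libraries, replicates 1 and 4 held 53.5% and 49.4% of their gene reads on the mitochondrial ribosomal RNAs, beside 39.6% in untreated replicate 3 and 0.165% to 11.8% in the other 9. The count of MT-RNR1 was higher with synta-66 than with CPA alone (log2 fold change 4.47 ± 0.91, adjusted p = 0.000659) and not without those 3 libraries (0.0989, adjusted p = 0.959). Without them 215 genes were higher and 392 lower, and 479 of the 710 calls remained, and the EGFR (adjusted p = 0.283), cholesterol (adjusted p = 0.1) and G2 and M (adjusted p = 0.106) lists were not called.

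Set against the CPA response, 130 of the 269 genes that CPA raised (48.3%) were called lower with synta-66 and 57 of the 156 that it lowered (36.5%) were called higher, 187 of 425 in all (44%). Independent lists would share 7.59 and 3.02 genes. A further 24 CPA-raised genes rose again and 1 lowered gene fell again, where independent lists would share 5.21 and 4.4. These are counts of all tested gene rows, and 159 of the 425 are long noncoding RNAs. Among genes read at opposite features, 73 of the 136 raised were called lower and 17 of the 52 lowered were called higher. There, 8 raised genes rose again and 1 lowered gene fell again. Both comparisons contain the same CPA libraries, so 20 sets of counts were simulated with no synta-66 effect. At most 2 genes were called in the second comparison of any set, so the simulated share called the opposite way, at most 0.091%, was bound to be low and does not measure what the shared libraries add. The log2 fold changes of the 2 comparisons had r = -0.506 and a covariance of -0.423 across genes. In the simulations r had a median of -0.284 and the covariance one of -0.19, and the difference of covariances was -0.233. With different CPA libraries, 2 and 2, used for the 2 comparisons, the share was between 35.2% and 37.8% over 6 choices, r between -0.227 and -0.164 and the covariance between -0.264 and -0.202. Of the 269 raised genes, 73 were still called higher than untreated with synta-66 and 188 were not called different from untreated; 16 of the lowered genes were still called lower.

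Among genes called in 2 CPA and 2 untreated libraries and measured in the other libraries, synta-66 removed a median of 63.3% of the rise (56.8% to 71.1% over 36 choices of libraries) and 83.6% of the fall (55% to 159%). Taking the median of the ratio per gene gave 80.4% for the rise. Leaving out single libraries moved the share of genes called the opposite way between 38.2% (without CPA with synta-66 replicate 3) and 46.2% (without CPA replicate 1), and it was 39.1% without the 3 libraries named above.

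**Figure D2:**
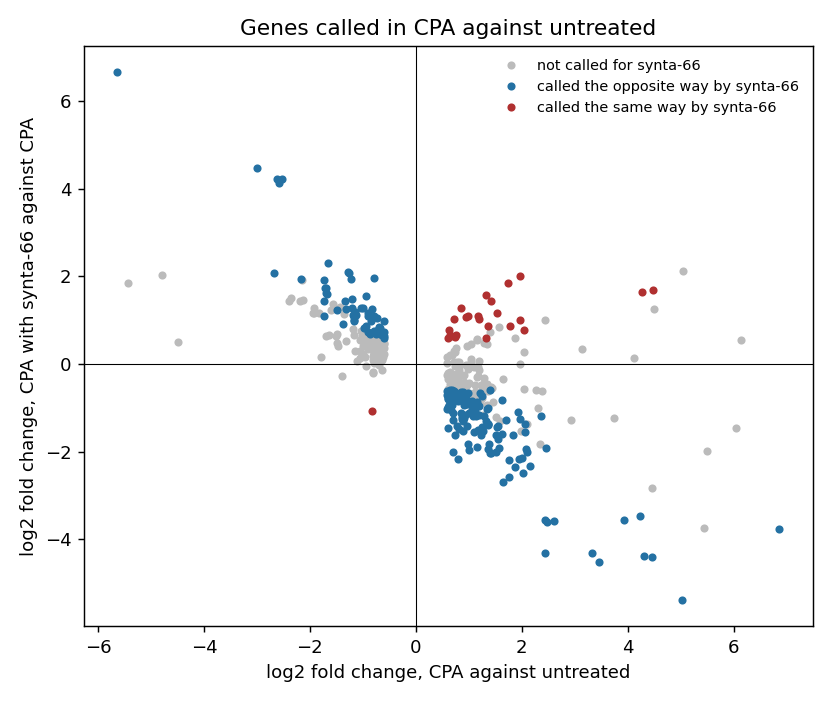
Log2 fold change of CPA against untreated (x axis) and of CPA with synta-66 against CPA (y axis) for the 425 genes called in the first comparison, 1 point per gene. Blue points (187) were called the opposite way by synta-66, red points (25) the same way and grey points were not called; fitted values of genes with almost no reads in a group are not bounds.

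The third comparison sets CPA with synta-66 against untreated cells. Read at opposite features, the secretory-cell transcription factor BHLHA15 (at TECPR1) rose from 5.97 ± 1.19 to 94.8 ± 15.2 CPM and EIF2AK3, the gene of the stress kinase PERK, from 161 ± 16 to 670 ± 41.8 CPM. The feature MARS1, which lies opposite both ARHGAP9 and DDIT3, the gene of CHOP, rose from 213 ± 8.42 to 2570 ± 162 CPM, and which of these it reads could not be assigned. CYP1B1 fell from 35.2 ± 7.41 to 4.87 ± 1.38 CPM, the triglyceride enzyme DGAT2 from 29.9 ± 5.83 to 7.86 ± 1.48, and the chromatin protein HMGA2 from 258 ± 58.1 to 107 ± 11.1. In the edgeR test 248 genes were higher and 185 lower, and 114 and 51 of those read at opposite features, with adjusted p = 1.06e-19 for BHLHA15, 1.14e-22 for EIF2AK3 and 5.59e-33 for the feature MARS1.

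Of the 12 endoplasmic reticulum genes read at opposite features, 7 rose and none fell, both over all genes and adjusted over the list alone: HSP90B1 (2.83 ± 0.14), HYOU1 (1.75 ± 0.08), SYVN1 (1.49 ± 0.20), EDEM1 (1.05 ± 0.14), CALR (0.92 ± 0.07), PDIA6 (0.75 ± 0.07) and PPIB (0.69 ± 0.07). The list rose (adjusted p = 2.9e-09; adjusted p = 0.00157 with an estimated correlation). By their own counts 9 of 25 rose, 10 rose and 2 fell adjusted over the list alone, among them HSPA5 (1.94 ± 0.29) and HSP90B1 (0.91 ± 0.16) but not SYVN1 (-0.11 ± 0.13), with list adjusted p = 0.000222, but adjusted p = 0.454 with an estimated correlation and 0.096 without the 3 libraries richest in non-unique alignments. HERPUD1, of endoplasmic reticulum degradation, had 1 read over the 4 untreated libraries, 35 with CPA and 68 with synta-66. The ratio to untreated was 5.46 to 1320 and 14.6 to 3370 (95% intervals that take each read as independent, counting error only). These intervals are too narrow if the 2 reads of a pair were counted singly. The ATF4 and CHOP list rose by own counts (3 of 21 members, adjusted p = 7.37e-05; adjusted p = 0.0667 with an estimated correlation) and at opposite features (4 of 8, adjusted p = 0.0245; adjusted p = 0.084 with an estimated correlation). At opposite features angiogenesis and hypoxia (adjusted p = 0.00187), pain mediators (adjusted p = 0.0269) and immediate early genes (fall, adjusted p = 0.0219) were also called, with adjusted p = 0.0542, adjusted p = 0.084 and adjusted p = 0.084 with an estimated correlation. By own counts these lists had adjusted p = 0.984, 0.95 and 0.632, and of their 19, 14 and 17 members only CXCL8, a pain mediator, was called. The calls ended without untreated replicate 2 for pain mediators and for ATF4 and CHOP genes (0.0525 each), without CPA with synta-66 replicate 1 for pain mediators (0.0725) and without replicate 2 of that group for immediate early genes (0.0566). IL6 read at its opposite feature was higher than in untreated cells (1.76 ± 0.22), and its own count was not called (0.165 ± 0.436, adjusted p = 0.927). Without the 3 libraries 198 genes were higher and 142 lower, and 269 of the 433 calls remained.

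**Figure D3:**
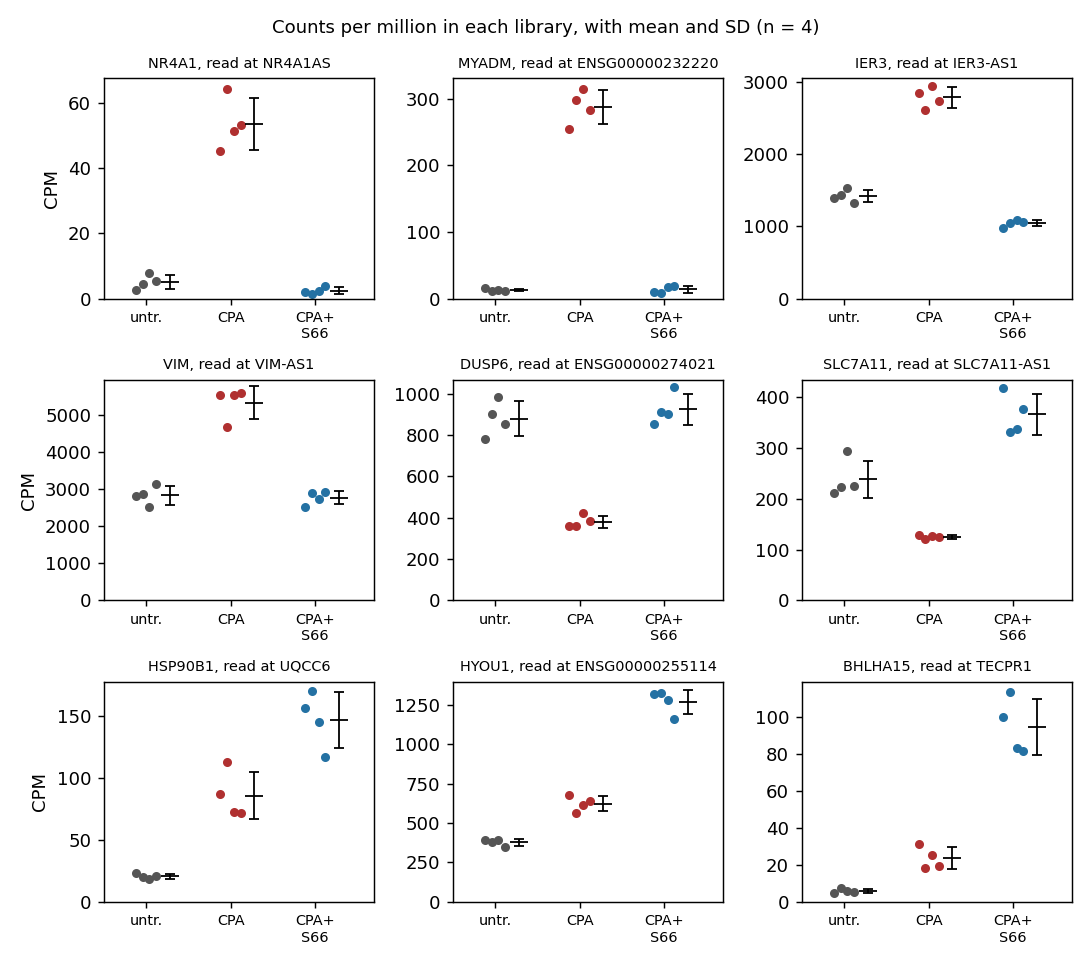
CPM values (TMM-scaled) of 9 genes read at an opposite feature, 1 point per library, with the mean and SD of each group of 4 libraries at the right of its points. NR4A1, MYADM, IER3 and VIM were higher with CPA and lower with CPA and synta-66, DUSP6 and SLC7A11 the reverse, and HSP90B1, HYOU1 and BHLHA15 rose from untreated to CPA and again to CPA with synta-66.

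For the channel and pump genes themselves the own counts were low. No feature met the rule for reading ORAI1, ORAI3, STIM2, ATP2A2, RCAN1, MMP1, ANGPTL4, CSF2 or CXCL8 at the opposite strand. Abundant genes such as ACTB also had few reads of their own. Low own counts therefore do not show that these genes are weakly expressed or unchanged. ORAI3 and STIM2 reached at most 4 reads in any library, RCAN1, a calcineurin target, at most 6 and CSF2 at most 8, and none of these 4 was tested. ORAI1 (0 to 16 reads per library), ORAI2 (51 to 173), STIM1 (3 to 25), the CPA target ATP2A2 (18 to 67), MMP1 (6 to 24), ANGPTL4 (4 to 28) and DDIT3 by its own count (324 to 699) were tested and called in none of the 3 comparisons. The SE of their log2 fold changes lay between 0.112 for DDIT3 and 0.78 for ORAI1. By the rule used here the own count of ORAI2 is also the reading of ALKBH4. That of DDIT3 lies opposite MARS1 and MBD6. Neither own count can be separated from the transcripts opposite it. The features opposite STIM1 (STIM1-AS1) and ORAI2 (ALKBH4) had few reads and were also called in none of the 3 comparisons. The feature MARS1, opposite DDIT3 and ARHGAP9, was called higher with CPA (log2 fold change 1.74) and again with synta-66 (1.85). Which gene it reads could not be assigned, so a response of DDIT3 is not excluded. CXCL8 had 0 untreated reads, 16 with CPA and 26 with synta-66, at least 3.58-fold and 8.11-fold higher by the 95% limit of the ratio (counting error only). Over a floor of 3 reads over the group it was 4.95-fold and 10.7-fold higher. It was called against untreated with synta-66 (adjusted p = 0.0123) but not with CPA alone (adjusted p = 0.0625). Without the 3 libraries the synta-66 call for CXCL8 had adjusted p = 0.179, and without CPA replicate 4 CXCL8 was called with CPA alone (0.0343). Without untreated replicate 4 ATP2A2 was called for synta-66 against untreated (0.0355).

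NFAT and calcineurin targets, cytokines and chemokines, NF-kB targets, calcium entry and handling, G1 and S phase genes, keratinocyte differentiation, heat shock and interferon response genes were called as lists by camera in no comparison by either route with all 12 libraries. Fry, which asks whether a list's genes move and not whether they move more than others, called all of these but interferon response genes at opposite features for CPA against untreated, with adjusted p between 0.000611 (NFAT targets) and 0.0174 (heat shock). It also called NFAT targets (0.0308), G1 and S phase genes (0.000702) and keratinocyte differentiation (0.000802) for CPA with synta-66 against CPA. Against untreated with synta-66 it called NFAT targets (0.0383), cytokines (0.00187) and NF-kB targets (0.00378). For CPA against untreated at opposite features, NFAT targets were called without untreated replicate 1 (adjusted p = 0.0431) or 3 (0.0146), CPA replicate 1 (0.049) or 3 (0.0319), or the 3 libraries (0.0236). Cytokines were called there without untreated replicate 1 (0.0327), CPA replicate 4 (0.0488) or CPA with synta-66 replicate 3 (0.0477). They were also called for CPA with synta-66 against untreated without untreated replicate 1 (0.0395) or CPA replicate 3 (0.0449). For CPA with synta-66 against untreated, NF-kB targets were called at opposite features without untreated replicate 3 (0.0225) or CPA with synta-66 replicate 2 (0.028). By own counts they were called without untreated replicate 4 (0.00637) or CPA with synta-66 replicate 1 (0.047) or 4 (0.0392). At opposite features, G1 and S phase genes (0.0489) and EGFR ligands (0.0242) were called for CPA with synta-66 against CPA without CPA replicate 2. By own counts EGFR ligands were called for CPA against untreated without untreated replicate 1 (0.0454) or 3 (0.0299), or the 3 libraries (0.0426). By own counts 20 lists were tested and the uncalled ones had adjusted p between 0.102 and 0.967 for CPA against untreated, 0.0672 and 0.982 for CPA with synta-66 against CPA, and 0.101 and 0.984 for CPA with synta-66 against untreated. At opposite features 19 lists were tested, with 0.0551 to 0.762, 0.0554 to 0.998 and 0.102 to 0.84. Own counts called 1, 2 and 2 lists and opposite features 8, 5 and 5, of which an estimated correlation kept 0, 1 and 0 and 5, 0 and 1. Of the markers of other cell types, 1 fibroblast gene and 3 immune or endothelial genes of 12 and 16 passed the count filter by their own counts and none was called.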

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

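The test on MT-ND6 was written down before its value was seen, and the other tests of explanations in this part were chosen after the results were seen. The list test by own counts with all 12 libraries and the estimated correlation had been planned. The rule that reads the MT-ND6 value was itself made stricter after that value was seen, from a ratio above 1 to a ratio above 1 in at least 10 of the 12 libraries, which left it undecided where the first rule would have counted it in favour.

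The reads of 8 of 13 coding genes examined lay mainly at a feature on the opposite strand. EEF1A1, with few reads at either place and an overlap of 119 bases, went the other way, and ACTB, TUBA1B, KRT5 and KRT14 had no such feature. Libraries that do not mark strand would put similar numbers of reads on both strands. In the 8 genes the mean at the gene itself was between 0.0603% and 1.84% of that at the opposite feature. This argues against such libraries for these genes. The median ratio of the noncoding feature to its coding gene was 11.1, but only features that passed the count filter entered, which raises it. Antisense transcription by the features themselves would leave the coding genes' own counts high, and ACTB, which growing cells express strongly, had a mean of 14.8 CPM, which argues against that as the whole cause. Counting on the strand opposite to the one the libraries mark may account for the pattern and stays open: MT-ND6, the only coding gene on the other mitochondrial strand, had 1.19 times the median reads of the other 12, between 0.742 and 2.35 over libraries and above 1 in 9 of 12, and 5 of those 12 genes had more reads than it. MT-ND6 cannot decide this, since the means of those 12 genes themselves ranged from 20.4 to 4060 reads. Between 90.5% and 96.3% of uniquely aligned reads lay in no annotated feature. Counting on the other strand would also give that, but it was not set as a test. The library kit is not named in the sources used here, so the strand setting could not be settled.

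Endoplasmic reticulum genes read at opposite features were higher with synta-66 than with CPA alone (adjusted p = 0.0053, camera). Without the 3 libraries richest in non-unique alignments the list had adjusted p = 0.0318, and with mitochondrial and unmatched genes left out 0.00555, so neither is the whole cause of this list's call. The pattern itself is not firm, since it had adjusted p = 0.0764 with an estimated correlation, and by own counts, for CPA with synta-66 against CPA, ER chaperones and ERAD had adjusted p = 0.0672 and 0.35 without those libraries. A biological hypothesis is that less calcium entry leaves the endoplasmic reticulum emptier under CPA, and 9 of 12 list members were above 0 in both comparisons, a count that decides nothing, since the list had been called in both and they share the CPA libraries. Synta-66 acting by itself would give the same values, and without a group given synta-66 alone the explanations cannot be told apart.

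Mitochondrial ribosomal RNA was higher with synta-66 than with CPA alone (MT-RNR1, log2 fold change 4.47). Without the 3 libraries richest in non-unique alignments the log2 fold change was 0.0989, but these are also the 3 with the highest share of this RNA, so leaving them out fixes that outcome and decides nothing. Ribosomal RNA left in some libraries whatever the treatment stays open, as does an effect of synta-66: 2 of the 4 synta-66 libraries had a larger share than every CPA library, and the other 2 lay within the CPA range.

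In 276 groups of 4 libraries, over 83 features printed in the text and 9 measures of the libraries such as depth, 16 held a library far from the other 3 by Dixon's criterion (the gap to the nearest library over the range), and chance gives 13.8. CPA replicate 3 had 20.3 CPM at LIF-AS2 (LIF), where the others had 10.8 to 12.4, and 3.48 CPM for SHMT2 (others 6.19 to 6.47). CPA replicate 2 was low at VIM-AS1 (4659 against 5526 to 5592 CPM) and at PHLDA1-AS1 (949 against 1060 to 1074), and high at STARD5, read for IL16 (7.91 against 3.87 to 4.32), and at HMGA2-AS1 (355 against 156 to 176). Untreated replicate 3 was high at SLC7A11-AS1 (293 against 212 to 225 CPM), at ENSG00000261266, read for PLK1 (89.1 against 75.3 to 77.6), and for MT-RNR1 (218416 against 2827 to 36204). Untreated replicate 4 was high for AREG (9.08 against 2.71 to 3.4 CPM) and PDIA4 (14.6 against 3.2 to 4.69), and untreated replicate 2 at MARS1 (226 against 208 to 210). HERPUD1 had 0.208 CPM in untreated replicate 1, where the others had 0, and 4.64 CPM in CPA replicate 1 (others 0.93 to 1.43). HSP90B1 by its own count had 79 CPM in CPA replicate 1 (others 48.7 to 51.8). RET had 3.88 CPM in CPA replicate 4 (others 1.43 to 1.81).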

How the results depend on the processing

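The fits without 3 libraries, the fit without mitochondrial and unmatched genes, all values at opposite features and the counts over other splits were chosen after seeing the data, and the other alternatives before. No named gene or list reversed under any alternative run: of 4593 alternative values of 200 called gene comparisons 4295 kept the call and 298 lost it, 119 never lost it, and 12 of 1271 values of the 56 uncalled ones gained it. DESeq2 called 305 higher and 203 lower for CPA against untreated, 339 and 464 for CPA with synta-66 against CPA, and 265 and 220 for CPA with synta-66 against untreated. A test against the minimum fold (glmTreat) called 82 and 18, 53 and 104, and 79 and 23, since it asks for more than the minimum. Without a minimum fold 261 genes were lower with CPA and 515 higher with synta-66 than with CPA. Leaving out 1 library gave 218 to 281 higher and 125 to 160 lower, 244 to 312 and 323 to 472, and 205 to 254 and 130 to 177. The share of CPA-called genes called the opposite way was 45.2% with no filter, 48.5% with no minimum fold, 46% with glmTreat, 45.6% with 2 groups per fit, 38.2% to 46.2% without 1 library and 39.1% without the 3 libraries, and the cause was not tested. The share of the CPA rise removed was 80.4% as the median ratio per gene and 61.4% to 65.8% without 1 library, and that of the fall 76.1% to 91.2%. With mitochondrial and unmatched genes left out 404, 712 and 419 genes were called, 398, 681 and 411 of them also in the fit with all genes. Lists called by own counts (1, 2 and 2) became 0, 1 and 0 with an estimated correlation, 0, 2 and 1 with fry, 2, 1 and 1 without the 3 libraries, and 0 to 2, 1 to 3 and 2 to 3 without 1 library. At opposite features (8, 5 and 5) they became 5, 0 and 1, 18, 12 and 10, 7, 3 and 5, and 7 to 9, 3 to 7 and 3 to 6. Fry asks whether a list's genes move, not whether they move more than others. The replicate numbers gave no clear pairing of the libraries. Deviations of libraries with the same number had r between -0.0237 and 0.054 (mean 0.0118). With different numbers r lay between -0.0712 and 0.0786 (mean -0.0039). Of 12 libraries, 5 correlated best with their own number. Such low r cannot exclude a pairing. With the replicate number as a block 283 and 158, 292 and 431, and 236 and 182 genes were called, the share called the opposite way was 43.8%, and lists by own counts were 0, 2 and 2. Of the 35 splits of the 8 libraries of each comparison, 1 called as many genes as the real one, the real split itself. It called 451, 756 and 393 genes against at most 5 in any other, a share of 1 in 35, the smallest this test can give. The other splits mix both groups on each side, so few calls there follow from any difference between the groups. A difference in culture or preparation would give the same, so the test cannot tell it from a treatment effect. In simulated data 3 to 7 of 50 genes changed 1.5-fold, which is also the minimum for a call, and 38 to 41 of 50 changed 8-fold were recovered. Low counts limit smaller changes: of genes changed 2-fold, 19 of 22, 15 of 20 and 13 of 19 with a mean of at least 10 CPM were recovered in the 3 comparisons, against 0 of 28, 0 of 30 and 2 of 31 below it.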

Other observations

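Among the 24 genes that CPA raised and synta-66 raised again, further to HSP90B1, HYOU1, BHLHA15, EIF2AK3 and the feature MARS1, was the zinc finger gene ZNF165, read at its opposite feature, from 61.6 ± 3.94 untreated to 165 ± 19.2 with CPA and 444 ± 43.7 CPM with synta-66 (SD, n = 4). WIPI1, an autophagy gene read in the same way, rose from 4.28 ± 0.977 to 9.72 ± 3.9 and 19.7 ± 3.02 CPM, and DNAJB9, a chaperone, by its own count from 18 ± 4.11 to 27.3 ± 4.39 and 41.1 ± 2.91 CPM. The pentraxin PTX3, read at VEPH1, had log2 fold changes of 0.76 and 0.67 in the 2 steps. These genes were taken from the 24 after their values were seen. Low own counts, here and below, may not show a gene's expression. Other genes lower with synta-66 than with CPA, in the edgeR test, included PAX8 by its own count, at 22.9 ± 4.79 CPM with CPA and 4.84 ± 1.75 with synta-66 (adjusted p = 5.44e-07), though not at its opposite feature PAX8-AS1 (adjusted p = 0.936), and CCDC85B by its own count, at 181 ± 50.4 and 74 ± 12.7 CPM (adjusted p = 2.81e-09).

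The following test was chosen after the 24 genes were seen. Of the 24, 3 were in the endoplasmic reticulum or ATF4 lists (DNAJB9, HSP90B1 and HYOU1), and of the 130 that CPA raised and synta-66 lowered 0 were, an exact Fisher p of 0.00339 (two-sided). The endoplasmic reticulum list had already been called higher at opposite features in both comparisons, so the test restates that result and decides nothing further. The second of those calls had adjusted p = 0.0764 with an estimated correlation, and by own counts the list was called in neither (adjusted p = 0.25 and 0.0672).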
